A study of Mus musculus with 10 samples.

How the data were processed

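Nuclei from punches of the ventral tegmental area (VTA), the midbrain region that holds a large part of the brain's dopamine neurons, were profiled by single-nucleus RNA sequencing on the 10x Genomics Chromium v3 platform. In this assay each captured RNA molecule carries a unique molecular identifier (UMI), so that molecules and not amplified copies are counted. The mice were wild-type C57BL/6. Per the labels there were 10 samples: 3 control male, 3 control female, 1 hungry male, 1 hungry female, 1 sated male and 1 sated female. Hungry mice had been fasted for 16 h and sated mice had been fed sweetened condensed milk beforehand, and the labels give no treatment for the controls. Each sample pooled punches of 2 mice of one sex and condition that had been paired at random, so samples are separate animals, and the spread between samples is a spread between pools of 2.

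The deposited values were UMI counts per gene and nucleus barcode, made by the authors with Cell Ranger on the mm10 mouse build, per the submitters' processing notes. Per the file headers, the 6 control files came from Cell Ranger 6.1.1 and the 4 hungry and sated files from Cell Ranger 7.1.0, whereas the notes name 6.1.1. The later version counts intronic reads unless told otherwise, and whether they were counted in either set is not given in the sources used here. Software version and control status go together in all 10 samples. Every comparison with controls compares condition and counting software at once. Hungry and sated files share 1 version, and both sexes are present under each version. The files listed 31053 genes, the same in every sample, with Ensembl identifiers and symbols. Coordinates were looked up by identifier in the GENCODE M21 annotation of mm10 (GRCm38). Whether counting used the strand is not given in the sources used here, so values of antisense and overlapping genes, and of genes with near-identical copies such as those of ribosomal proteins, are uncertain.

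The files held 133283 barcodes. Nuclei with at least 500 detected genes and at most 5% mitochondrial UMIs passed (118845). Doublets were called per sample with the Scrublet implementation of scanpy 1.11.5 at an expected rate of 8%, and 6349 nuclei (5.34%) were left out, between 2.79% and 7.84% per sample. For control female 2, where the automatic threshold marked almost no nucleus, the median threshold of the other samples was used. The remaining 112496 nuclei, together with the called doublets, were clustered on variable genes chosen with a setting of 2000, centred within sample, with 30 principal components, 15 neighbours and the Leiden method of igraph 0.11.9 at resolution 1.0, and neurons were clustered again at resolution 1.5. The feeding-hormone, social-hormone, immediate early, glucocorticoid-responsive and clock lists, the mitochondrially encoded genes, Xist, Tsix and Y-linked genes were kept out of the variable genes.

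Of 66 clusters, 48 were named from marker lists fixed in advance. A name needed more than 50% and at least 3 of a list's markers at 2 times the level of the median cluster in at least 10% of nuclei. A cluster stayed unnamed where 25% or more of its nuclei were called doublets, where 1 sample gave 80% or more of them, or where another class had more markers than its own among its 10 top genes. Neuron clusters that met no list were named other neuron when at least 3 general neuronal markers were each seen in at least 50% of nuclei, and the limit on top genes was not applied to them. These limits were set after the clusters had been seen. The 18 unnamed clusters held 8.49% of the kept nuclei: 9.02% ± 5.93 (SD, n = 6) in controls, 12.2% in the hungry male, 6.92% in the hungry female, 9.24% in the sated male and 6.20% in the sated female. Dopaminergic markers led 4 of them, with 3.98% ± 2.92 (SD, n = 6) of nuclei in controls, 5.72% and 4.68% in the hungry male and female, and 2.18% and 2.46% in the sated male and female. The largest of these, with 3603 nuclei, called doublets included, carried 9 of 10 dopaminergic markers. None of them was among its 10 top genes, where Bnc2, a marker on the fibroblast list, stood. Bnc2 was also among the 10 top genes of the named dopaminergic clusters N2 and N9. The cluster was left out of the dopaminergic class and added back in an alternative chosen after the data had been seen. Of its kept nuclei and those of the class together, it held 52.8% and 47.8% in the hungry male and female. The share was 28.4% and 32.2% in the sated male and female and 27.7% to 51.6% in controls. Cluster borders shifted with the random seed, so a clustering with another seed was also carried through all tests. An earlier trial of the same clustering under other numerical settings had a further dopaminergic cluster and gave several times as many genes for hungry against sated mice. It could not be rebuilt exactly, so its values are not given.

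Raw counts were summed per sample and class. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by condition, robust), with condition and sex as terms, on all 10 samples in 1 fit, for each of the 9 classes with at least 10 nuclei in every sample. With 1 hungry and 1 sated sample per sex, the spread rests largely on the 6 controls. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. Adjusted p-values of single genes are from this test throughout. Log2 fold changes are given with their standard error (SE), and levels as CPM, the counts of a gene scaled to the total of a class in a sample. Tests of whether the feeding contrast differed between the sexes added an interaction term. With 1 hungry and 1 sated sample per sex, the spread in these tests comes from the 6 controls alone. Gene lists were tested on the same sums with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated, and with fry, all two-sided. They were feeding-hormone, social-hormone, immediate early, glucocorticoid-responsive, circadian clock, insulin and FoxO response, fatty acid and ketone metabolism, cholesterol synthesis, dopamine handling, glutamate and GABA receptor, potassium channel, neuropeptide, stress and heat-shock, mitochondrially encoded, oxidative phosphorylation and dopamine subtype genes, and markers of GABAergic neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and endothelial cells. These are 22 lists. Glutamatergic markers were measured too rarely in dopaminergic nuclei to be tested.

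The tests, the gene lists, the cell type markers and the rule for naming genes were fixed before the data were examined. For hungry against sated, for hungry and sated together against control and for female against male, the genes named are up to 10 rising and 10 falling genes of lowest p that passed and had the same direction in both sexes (for the sex contrast, in controls and in the other samples). Where fewer than 5 passed in a direction, those of lowest p up to 5 are named as not passing. For hungry or sated alone against control they are 5 in each direction, and in each other class 3 in each direction. Members of a list that passed, and Th, Slc6a3, Fos, Lepr, Insr, Ghsr, Oxtr and Esr1, are named in any case, and Xist and Y-linked genes check the sex labels. Some genes that fall under these rules are not reported here. Other list members given as examples, Cartpt, and all list members outside dopaminergic nuclei were chosen after their values had been seen.

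For co-expression, each dopaminergic nucleus was thinned to 2000 UMIs. Shallower nuclei (847, of which 365 were in control female 2) were left out, and 3870 were used. Per sample, the number of nuclei with at least 1 UMI of the feeding-hormone list (21 genes) and at least 1 of the social-hormone list (11 genes) was divided by the number that independence of the shares would give, and the 10 log2 ratios were tested with a two-sided exact sign-flip permutation test. For comparison, 1000 random pairs of lists were matched gene by gene on detection. Pairs of genes, 1 from each list, were tested in the same way. Class shares were compared between 5 female and 5 male samples with a two-sided exact permutation test.

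Total UMIs per sample ranged from 16804500 to 40577036, with a median of 1277 to 2293 UMIs per passing nucleus in each sample. On counts simulated from these samples with 12831 genes, the hungry against sated test recovered 8.96% of genes changed 1.5-fold, 38.8% of those changed 2-fold and 83.3% of those changed 4-fold, with 11 false calls of 98. The test of both against control recovered 38.8%, 79.1% and 95.5%, with 13 false calls of 155, and the female against male test 31.3%, 83.6% and 95.5%, with 7 of 147. The share of false calls was above the nominal 5% in the comparisons of feeding state. Of 200 unchanged lists, camera gave p under 0.05 for 3, 4 and 2 in these 3 contrasts. Genes were simulated independently of each other, so this does not measure false calls for lists whose members vary together. In the samples the estimated correlation was 0.705 for oxidative phosphorylation and 0.898 for mitochondrially encoded genes in hungry against sated mice. The co-expression test gave a mean log2 ratio of −0.009 where none was simulated and 0.539 where 0.585 was.

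Alternatives fixed in advance were RLE size factors, no low-count filter, DESeq2 1.42.0, doublets kept, at least 1000 genes per nucleus, each sample left out, the replicate number as a block between the sexes, controls alone, the 4 hungry and sated samples alone, no sex term, and for co-expression no thinning, thinning to 1000 UMIs, 2 UMIs per list and lists without their most detected gene. Alternatives added after the data had been seen were another clustering seed, the left-out dopaminergic-like cluster included, the same mix of dopaminergic clusters in every sample, each such cluster alone, ribosomal, mitochondrial and haemoglobin genes left out, co-expression expected within clusters, and every alternative for glucocorticoid-responsive genes outside dopaminergic nuclei. In the fits of controls alone the low-count filter was grouped by sex. Pericyte and mural nuclei, too few in several samples, entered shares only. Free RNA in the droplets was not removed.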

Results

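Nuclei of the mouse VTA were counted in 10 samples, each a pool of 2 animals: 6 control samples (3 male, 3 female), 2 hungry samples (1 male, 1 female, fasted for 16 h) and 2 sated samples (1 male, 1 female, fed sweetened condensed milk). Total UMIs per sample were 31577961, 22660377 and 31257944 in control males 1 to 3 and 23268559, 16804500 and 40577036 in control females 1 to 3. The hungry male held 25067466, the hungry female 31366526, the sated male 39889735 and the sated female 23987906. After filtering, 112496 nuclei remained. The study's title concerns how dopamine neurons of this region represent food and social stimuli, and the design allows comparisons of feeding state, of sex, and of the joint expression of receptors for feeding-related and social hormones.

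Dopaminergic nuclei, which expressed Th (tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis) and Slc6a3 (the dopamine transporter), numbered 4717 without the left-out dopaminergic-like cluster. At least 1 UMI of Th was present in 77.6% of them and of Slc6a3 in 77.1%, at a median of 3388 UMIs per nucleus, against 11.0% and 14.5% of oligodendrocyte nuclei at a median of 981 UMIs. The class was made up of 3 clusters: cluster N24, marked by Aldh1a1 and Otx2, cluster N2, marked by Sox6, and cluster N9, marked by Calb1. Cluster N24 was the largest of them in every sample, with 43.0% to 68.9% of dopaminergic nuclei in controls, 35.6% and 40.9% in the hungry male and female, and 61.5% and 54.8% in the sated male and female. Cluster N9 held 30.5% and 24.3% in the hungry male and female and 16.0% and 20.2% in the sated male and female. The other classes were oligodendrocytes (34920 nuclei), other neurons (21473), GABAergic neurons (16075), astrocytes (15900), oligodendrocyte precursors (4738), microglia (2687), endothelial cells (1287), fibroblasts and meningeal cells (930) and pericytes and mural cells (214).

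Hungry and sated samples were compared to ask how feeding state changes gene expression in dopamine neurons. In dopaminergic nuclei, the neurofilament genes Nefl and Nefm, Pvalb and the glycolytic gene Aldoc were lower in hungry than in sated mice, and Rbm20 was higher. Genes that fell here also had negative fold changes in nearly every other class, as given below. Free RNA in the droplets was not removed, so these values need not come from dopaminergic nuclei alone. Pvalb, the calcium buffer parvalbumin, stood at 2.02 and 1.68 CPM in the hungry male and female against 23.5 and 19.4 in the sated male and female (log2 fold change −3.53, SE 0.444, adjusted p = 0.00286), with 10.9 ± 2.48 CPM (SD, n = 6) in controls. The light and medium neurofilament chains Nefl and Nefm fell by 2.11 (SE 0.303) and by 1.80 (SE 0.258) on the log2 scale, both at adjusted p = 0.00571. Between the sated and the hungry male and female, the levels went from 61.3 and 51.6 to 16.1 and 10.5 CPM for Nefl and from 47.3 and 34.2 to 11.4 and 12.2 CPM for Nefm. Controls held 36.7 ± 12.5 CPM of Nefl and 20.7 ± 2.38 CPM of Nefm (SD, n = 6). In the opposite direction, Rbm20, a splicing regulator best known for titin, was at 35.7 and 33.2 CPM in the hungry male and female, 8.66 and 10.7 CPM in the sated ones and 16.9 ± 4.28 CPM (SD, n = 6) in controls (log2 fold change 1.83, SE 0.303, adjusted p = 0.0201).

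Of 12831 genes tested, 3 rose and 14 fell in hungry against sated mice (edgeR, adjusted p under 0.05), and all 17 had the same direction in both sexes. The test itself favours such genes, since opposite changes in the sexes widen the spread of the fit. Besides Rbm20, the rising genes were Flrt3, a membrane protein of axon guidance and synapse formation (0.66, adjusted p = 0.0464), and Colgalt1, a collagen galactosyltransferase (0.99, adjusted p = 0.0486). Tifa (0.78, adjusted p = 0.0517) and Mipol1 (0.75, adjusted p = 0.0567) came next and did not pass. Falling genes included Aldoc, a glycolytic aldolase (−1.56, SE 0.219, adjusted p = 0.00571), the cytochrome c oxidase subunit Cox8a (−1.0, SE 0.149, adjusted p = 0.00571), the ferritin heavy chain Fth1 (−1.31, adjusted p = 0.0352) and transferrin, Trf (−1.69, adjusted p = 0.0464), an iron carrier that oligodendrocytes also make. The tubulin gene Tuba4a (−1.37, adjusted p = 0.0352) and the dynein light chain Dynll2 (−1.03, adjusted p = 0.0464) fell as well. In mm10, Nefl lies on chromosome 14 at 68083863 to 68089095 on the plus strand, inside the annotated span of Nefm (68082590 to 68124846, minus strand), so reads of these genes cannot be told apart with certainty where strand was not used. Pvalb lies on chromosome 15 at 78191114 to 78206400, Aldoc on chromosome 11 at 78322968 to 78327781, Rbm20 on chromosome 19 at 53677306 to 53867080 and Cox8a on chromosome 19 at 7215153 to 7217616. Genes of the dopamine system and hormone receptors did not pass: Th −0.25 (adjusted p = 0.582), Slc6a3 0.25 (0.657), Insr 0.20 (0.724), Lepr 0.19 (0.767) and Esr1 −0.19 (0.899), as did the activity marker Fos −0.62 (0.870). Ghsr and Oxtr were detected too rarely to be tested.

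**Figure D1:**
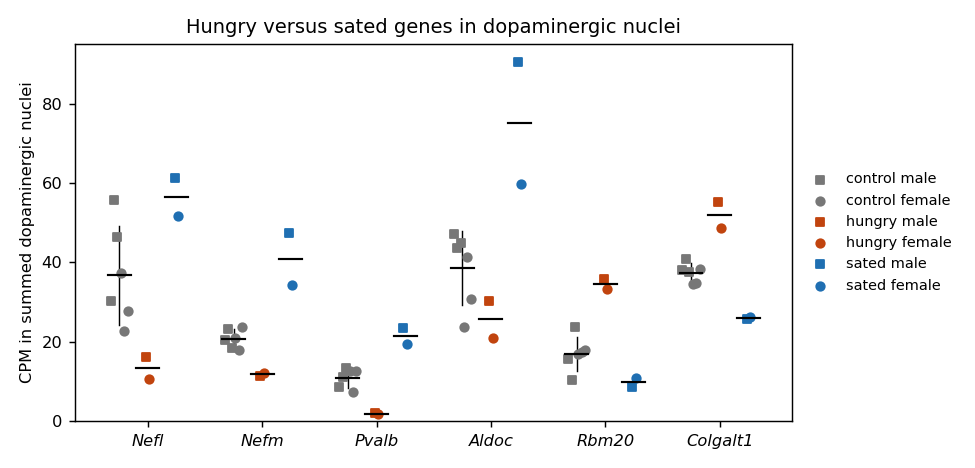
CPM in summed dopaminergic nuclei (vertical axis) of Nefl, Nefm, Pvalb, Aldoc, Rbm20 and Colgalt1 in each sample (horizontal axis, by gene), with conditions in colour (control in grey, hungry in red, sated in blue), with squares for male and circles for female samples, short horizontal bars for group means and vertical lines for the SD of the 6 controls. Both hungry samples lie below both sated samples for Nefl, Nefm, Pvalb and Aldoc, and above them for Rbm20 and Colgalt1.

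The number of genes called depended on single libraries. Without the hungry male no gene passed (0 with edgeR, 753 at unadjusted p under 0.05). The count was 4 without the sated male, 71 without the hungry female, 607 without the sated female, 7, 29 and 6 without control males 1 to 3, and 32 and 6 without control females 1 and 2. From the 4 hungry and sated samples alone edgeR called 0 genes (493 at unadjusted p under 0.05). On all 10 samples DESeq2 called 53.

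Among the lists fixed in advance, those of oxidative phosphorylation and of mitochondrially encoded genes lay lower in hungry than in sated dopaminergic nuclei. Of 23 nuclear genes of oxidative phosphorylation, 22 had a negative fold change (median log2 −0.79). None passed over all genes tested and 8 fell when adjusted over the list alone, with Cox6c at −1.18 (adjusted p over all genes 0.0555), Cox4i1 at −1.17 (0.0733) and Ndufa5 at −1.27 (0.0737). Camera gave adjusted p = 4.02e-11, and adjusted p = 0.303 with an estimated correlation. For some subunits outside this list the fitted change differed between the female and the male libraries, as for Ndufb7 and Ndufs6. Their female minus male log2 fold changes were 3.92 and 3.45. With 1 hungry and 1 sated sample per sex, a difference between libraries is not set apart from one between the sexes. All 13 mitochondrially encoded genes had negative fold changes (median −1.69, with mt-Nd1 at −1.71 and mt-Cytb at −1.87). None passed over all genes or adjusted over the list alone. Camera gave adjusted p = 1.37e-08, and adjusted p = 0.303 with an estimated correlation. Over all passing nuclei of each sample, the median mitochondrial share of UMIs was 0.681% and 0.592% in the hungry male and female, 1.77% and 2.03% in the sated male and female, and 0.142% to 1.80% in controls. Of 13 stress and heat-shock genes, 12 were lower (median −0.74), with Dnajb1 at −1.09 and Hsph1 at −0.75. None passed over all genes and 1 fell adjusted over the list alone (camera adjusted p = 2.62e-05, and adjusted p = 0.303 with an estimated correlation).

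Lists of neuronal function lay lower as well, and their camera calls were likewise lost, at adjusted p = 0.303 with an estimated correlation for each of the next 4 lists. Potassium channel genes had 15 of 22 members lower (median −0.22, camera adjusted p = 0.00442), with Kcnj3 at −0.85 and Kcnc1 at −0.76, and 4 fell adjusted over the list alone. Neuropeptide genes had 10 of 11 members lower (median −0.60, camera adjusted p = 0.00812), with 3 falling adjusted over the list alone. Values were −1.27 for Adcyap1, −2.05 for Vip and −6.57 (SE 1.84) for Cartpt, whose adjusted p over all genes was 0.284. Glutamate and GABA receptor genes had 20 of 26 members lower (median −0.14, camera adjusted p = 0.0332), with 0 passing adjusted over the list alone. Dopamine subtype genes, 16 measured, had a median of −0.37, 2 that fell adjusted over the list alone and camera adjusted p = 0.0418. Of 20 cholesterol synthesis genes 15 were lower (median −0.18), and 1 fell adjusted over the list alone, Scd2 at −0.73. Camera gave adjusted p = 0.0418, and adjusted p = 0.537 with an estimated correlation. No member of these lists passed over all genes tested.

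Lists of markers of other cell types also passed camera in the same dopaminergic nuclei, with no marker passing over all genes tested. The 8 oligodendrocyte markers had a median of −0.68, with Mal at −1.17 and Mbp at −0.89, and 4 of them fell adjusted over the list alone (camera adjusted p = 2.22e-04, and adjusted p = 0.303 with an estimated correlation). GABAergic markers (Gad2 −1.38, Gad1 −1.02, Slc32a1 0.11) had 2 of 3 falling adjusted over the list alone (camera adjusted p = 0.0305, and adjusted p = 0.303 with an estimated correlation). Astrocyte markers, 6 measured, had a median of −0.35, with 1 falling adjusted over the list alone, Slc1a2 at −0.40 (camera adjusted p = 0.0418, and adjusted p = 0.431 with an estimated correlation). Endothelial markers went the other way, with Pecam1 at 1.03 and Tek at 0.87, both rising adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.303 with an estimated correlation). Lists that did not pass camera were dopamine handling (adjusted p = 0.493), circadian clock (0.493), feeding-hormone (0.791), social-hormone (0.841), immediate early (0.791, with 1 member falling adjusted over the list alone), insulin and FoxO response (0.759), glucocorticoid-responsive (0.954), fatty acid and ketone metabolism (0.954), oligodendrocyte precursor (0.954) and microglia (0.155) genes. Median, mean and direction of the test differed in sign for the feeding-hormone, immediate early, glucocorticoid-responsive, fatty acid and oligodendrocyte precursor lists. By fry no list passed for a shared direction (lowest adjusted p 0.232) or for change in either direction (lowest adjusted p 0.0761).

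In the other classes of nuclei the same comparison found neurofilament and aldolase genes lower in hungry mice again. Nefl fell in GABAergic neurons (−1.66, adjusted p = 0.0131), other neurons (−1.58, 0.0304), microglia (−2.75, 2.82e-04) and endothelial cells (−2.07, 0.0166). Nefm fell in astrocytes (−2.46, 0.00487), oligodendrocyte precursors (−2.43, 5.46e-04) and endothelial cells (−3.06, 0.0338). Aldoc fell in GABAergic (−1.26, 0.0131) and other neurons (−1.38, 0.0277). All 14 genes that fell in dopaminergic nuclei had negative fold changes in GABAergic neurons, other neurons, astrocytes and microglia, 13 of 14 in oligodendrocytes and in oligodendrocyte precursors, and 12 of 12 measured in endothelial cells and in fibroblasts and meningeal cells. Some genes known from neurons were among those of lowest p that fell in glia: the synaptic vesicle protein gene Snap25 in astrocytes (−1.53, 0.00727), the calcium buffer Calb2 (−1.76, 0.0104) in oligodendrocytes, and Pvalb (−3.15, 0.00228) and the neuropeptide gene Cartpt (−6.57, 5.13e-05) in microglia. Cartpt stood at 5.94 and 0 CPM in microglia of the hungry male and female, 284 and 212 CPM in those of the sated ones and 27.4 ± 24.2 CPM (SD, n = 6) in controls. It fell in endothelial cells too (−5.67, 0.0166).

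Further genes changed in these classes, and no difference between classes was tested for them. In GABAergic neurons the transcription factor Mef2c (1.01, adjusted p = 0.0131), the guidance cue Sema3e (1.37, 0.0131) and the potassium channel partner Kcnip4 (0.71, 0.0295) rose, and Calb2 fell (−1.23, 0.0261). In other neurons the protease Pappa2 rose (2.33, 0.00263), with the antisense transcript 9130015G15Rik (1.2, 0.0210), and pyruvate kinase, Pkm, fell (−1.0, 0.0210). Astrocytes had higher 1700042O10Rik (2.93, 0.00487), Gm26776 (2.97, 0.0102) and the sulfotransferase Chst9 (1.12, 0.0169), and lower Got1, an aspartate aminotransferase (−1.49, 0.00487). Oligodendrocytes had higher 1700042O10Rik (1.63, 0.0151), Traf3ip2 (0.99, 0.0151) and A330015K06Rik (0.93, 0.0151) and lower C1ql1 (−1.73, 0.0104). The antisense transcript 1700042O10Rik was among the leading genes of all 3 dopaminergic clusters. Oligodendrocyte precursors had higher Hif3a (2.84, 0.00140), Tes (1.09, 6.22e-04) and Traf3ip2 (1.02, 0.00570) and lower Atp1b1, a subunit of the sodium pump (−1.35, 5.46e-04), and Cox8a (−1.38, 5.46e-04). In microglia Naaladl2 (2.27, 0.00518), Mast4 (1.59, 0.0118) and Gpc5 (3.06, 0.0253) rose. In fibroblasts and meningeal cells Dnah12, a dynein of motile cilia (−7.38, 3.04e-04), Adamts20 (−5.68, 2.71e-04) and 1700007G11Rik (−9.91, 1.22e-04) were lower in hungry than in sated mice, with the sated samples apart from controls too. Dnah12 stood at 697 and 508 CPM in the sated male and female, 5.21 and 0 CPM in the hungry ones and 3.8 ± 9.31 CPM (SD, n = 6) in controls. It is on the list of ependymal markers fixed in advance, and no cluster was named ependymal. Ependymal nuclei within this class cannot be told apart from a change in fibroblasts and meningeal cells. No UMI of 1700007G11Rik was seen in the hungry samples, so its fitted value is no bound.

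Counts of rising and falling genes were 33 and 49 in GABAergic neurons, 2 and 3 in other neurons, 39 and 135 in astrocytes, 105 and 284 in oligodendrocytes, 29 and 125 in oligodendrocyte precursors, 12 and 64 in microglia, 0 and 6 in endothelial cells and 0 and 61 in fibroblasts and meningeal cells (edgeR). DESeq2 called 2 genes in endothelial cells and 15 in fibroblasts and meningeal cells in either direction, and 358 and 390 had unadjusted p under 0.05 with edgeR. Without the hungry male the totals were 0 (1045 at unadjusted p under 0.05), 2, 1, 0 (1569), 9, 4, 0 (204) and 8 in these classes in turn. Without the sated female they were 1034, 711, 1222, 2160, 949, 721, 203 and 29. Without the hungry female they were 5, 1, 539, 628, 291, 381, 14 and 37. Without the sated male they were 11, 0 (1207), 137, 183, 37, 37, 6 and 22. Among controls, leaving out control male 3 gave 6 in GABAergic neurons, 75 in astrocytes, 111 in oligodendrocytes, 17 in microglia, 2 in endothelial cells and 120 in fibroblasts. Control male 1 gave 8 in other neurons, 112 in astrocytes, 145 in oligodendrocytes and 48 in microglia. Leaving out control male 2 gave 15 in other neurons. Control female 1 gave 46 in GABAergic neurons, 258 in oligodendrocytes and 39 in fibroblasts. Control female 2 gave 10, 102, 213, 116, 2 and 39 in GABAergic neurons, astrocytes, oligodendrocytes, microglia, endothelial cells and fibroblasts. Control female 3 gave 30, 95, 138, 38 and 0 (279 at unadjusted p under 0.05) in the first 5 of these.

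Hungry and sated samples together were compared with controls to ask what either manipulation of feeding did to dopaminergic nuclei. The RNA-binding protein gene Atxn2l fell, and the microRNA pathway gene Tnrc6c and the astrocyte genes Ndrg2 and Slc1a3 rose. Atxn2l, an RNA-binding protein of stress granules on chromosome 7 from 126491708, stood at 228 ± 51.5 CPM (SD, n = 6) in controls, 90.1 and 94.6 CPM in the hungry male and female and 71.8 and 104 CPM in the sated ones (−1.29, SE 0.139, adjusted p = 0.00140). Tnrc6c, a component of microRNA silencing, rose by 0.66 (SE 0.0852, adjusted p = 0.00151), from 232 ± 25 CPM (SD, n = 6) to 353 ± 45.9 (SD, n = 4). The control files were counted with another software version than the rest, which cannot be separated from the manipulation in any of these values. Free RNA was not removed, so RNA of astrocytes may be counted in the values of Ndrg2 and Slc1a3.

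In total 106 genes rose and 25 fell of 12831 (edgeR), all in the same direction in both sexes, which the test itself favours. Rising genes of low p were Tnrc6c, the antisense gene Gm42726 (1.48, adjusted p = 0.00140), Ccdc60 (1.86, 0.00178), the dynein intermediate chain Dync1i2 (0.54, 0.00522), and the astrocyte-enriched Ndrg2 (1.02, 0.00522). Further ones were the mitochondrial fission enzyme Dnm1l (0.51, 0.00791), Rpl26 (0.76, 0.00974), Paxbp1 (0.59, 0.00974) and Gm26859 (1.07, 0.00974). Values of Gm42726 and Rpl26 are uncertain because of overlap or near-identical copies. Besides Atxn2l, falling genes of low p were the secretory carrier protein gene Scamp5 (−0.62, 0.0159), the kinase Araf (−0.54, 0.0180), the ceramide synthase Cers2 (−0.94, 0.0235), and Sema4a (−0.73, 0.0241), with Tmem145 (−0.62, 0.0286), Tmem9b (−0.71, 0.0292), Stradb (−0.79, 0.0296) and Shisa4 (−0.60, 0.0296). Lepr 0.29 (adjusted p = 0.315), Th −0.08 (0.799), Insr −0.05 (0.899), Slc6a3 0.05 (0.904), Fos −0.14 (0.965) and Esr1 −0.0038 (0.998) did not pass. Leaving out 1 library gave 23 and 32 genes without control males 1 and 3, 58, 32 and 78 without control females 1 to 3, 42 without the hungry male and 228 without the sated female.

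Of 20 cholesterol synthesis and uptake genes, 19 had negative fold changes (median −0.24). Adjusted over the list alone, 4 fell and 1 rose (Scd1), with Hmgcs1 at −0.51 (adjusted p over all genes 0.0505) and Dhcr7 at −0.56 (0.0646). Camera gave adjusted p = 2.87e-05, and adjusted p = 0.374 with an estimated correlation. Of 10 glucocorticoid-responsive genes, 7 were higher (median 0.33). The metallothionein Mt2 (0.93, adjusted p = 0.0180), which has a close relative in Mt1, and the kinase Sgk1 (0.51, 0.0256) rose over all genes tested, and 4 rose adjusted over the list alone (camera adjusted p = 9.85e-04, and adjusted p = 0.339 with an estimated correlation). All 6 astrocyte markers were higher (median 0.54), with the glutamate transporter Slc1a3 passing over all genes (1.21, adjusted p = 0.0292) and 2 adjusted over the list alone (camera adjusted p = 9.85e-04, and adjusted p = 0.374 with an estimated correlation). The 3 GABAergic markers were lower (median −0.39), 1 of them passing adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.602 with an estimated correlation).

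Single members of lists that did not pass camera also rose: the stress-induced transcription factor Ddit3 (0.87, adjusted p = 0.0369) and the chaperone Hsph1 (0.54, 0.0417) of the stress list (camera adjusted p = 0.480), Trib2 (0.78, 0.0402) of the insulin and FoxO list (0.536) and the myelin gene Mobp (0.79, 0.0241) of the oligodendrocyte markers (0.610). Ddit3 did not pass with the left-out dopaminergic-like cluster included (adjusted p = 0.0957). Clock genes had 3 rising and 2 falling adjusted over the list alone and camera adjusted p = 0.176. By fry for change in either direction 6 lists passed: clock (adjusted p = 7.13e-07), glucocorticoid-responsive (0.00221), insulin and FoxO (0.00225), cholesterol synthesis (0.0216), astrocyte (0.0216) and fatty acid and ketone genes (0.0329). Camera adjusted p-values of the rest were 0.0638 for mitochondrially encoded genes (median 0.38), 0.0760 for microglia, 0.243 for endothelial, 0.876 for oligodendrocyte precursor, 0.302 for oxidative phosphorylation and 0.302 for neuropeptide genes. They were 0.392 for glutamate and GABA receptor, 0.579 for fatty acid and ketone, 0.868 for feeding-hormone, 0.940 for social-hormone, 0.876 for immediate early, 0.876 for dopamine handling, 0.880 for dopamine subtype and 0.940 for potassium channel genes. Median, mean and direction of the test differed in sign for the feeding-hormone, social-hormone, fatty acid, dopamine handling, potassium channel, oligodendrocyte and oligodendrocyte precursor lists.

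Against controls, hungry dopaminergic nuclei had 73 rising and 12 falling genes. Tnrc6c rose by 0.79 (adjusted p = 0.00451), Lrtm1 by 1.10 (0.00451), A530046M15Rik by 1.33 (0.00461), Ccdc60 by 2.03 (0.00461) and Gm42726 by 1.5 (0.00461). Atxn2l (−1.25, 0.00651), Araf (−0.78, 0.00689), Cox8a (−0.73, 0.00960), Pvalb (−2.49, 0.0103) and Nefl (−1.40, 0.0232) fell. Without the hungry male edgeR called 0 genes (810 at unadjusted p under 0.05), while DESeq2 on all samples called 86. The count was 158 without the hungry female, 252 without either sated sample, 41 and 50 without control males 1 and 3 and 38 and 42 without control females 2 and 3.

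Sated dopaminergic nuclei had 110 rising and 12 falling genes against controls. Ndrg2 (1.33), Rpl26 (1.08) and Fau (1.05) rose at adjusted p = 0.00346 and the cytoskeletal actin Actb (1.07) at adjusted p = 0.00415. Rpl26 and Fau encode ribosomal proteins with near-identical copies. Atxn2l (−1.33, 0.00498), Scamp5 (−0.76, 0.0141), Gm26699 (−0.56, 0.0267) and Tifa (−0.63, 0.0267) fell. The count was 17 without the sated male, 511 without the sated female, 48 without control male 1, 73 without control female 2 and 78 with ribosomal, mitochondrial and haemoglobin genes left out.

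Glucocorticoid-responsive genes were followed into the other classes after their values had been seen. They were higher in glial and vascular nuclei of hungry and sated mice than in controls. In oligodendrocytes all 15 measured members rose (median log2 1.66), among them the lipid droplet gene Plin4 (5.01, adjusted p = 1.72e-07), Sgk1 (3.33, 1.44e-05), Fkbp5, a co-chaperone that restrains the glucocorticoid receptor (3.07, SE 0.136, 4.35e-07), the transcription factor Zbtb16 (2.97), the cell cycle inhibitor Cdkn1a (2.5) and Tsc22d3 (0.73). Camera gave adjusted p = 4.02e-23, and adjusted p = 0.0210 with an estimated correlation. In astrocytes 12 of 15 rose (median 1.2, adjusted p = 0.00505 with an estimated correlation), with Fkbp5 at 3.8 (adjusted p = 4.31e-05), Sgk1 at 2.97 and Zbtb16 at 2.22. Members that rose numbered 8 of 11 in oligodendrocyte precursors (adjusted p = 0.0165 with an estimated correlation), 6 of 10 in microglia (0.00980; 3 without control male 1 or without control male 3) and 11 of 13 in endothelial cells (0.0262; 6 with DESeq2). All measured members had positive fold changes in fibroblasts and meningeal cells (10, median 0.98, adjusted p = 0.0199 with an estimated correlation), GABAergic neurons (14, median 0.52, 0.0378) and other neurons (14, median 0.43, 0.0441). In dopaminergic nuclei 7 of 10 did (median 0.33, 0.339). Few single members passed there: 1 in fibroblasts and meningeal cells, 2 in GABAergic neurons, 3 in other neurons and 2 in dopaminergic nuclei. None passed in fibroblasts and meningeal cells or in GABAergic neurons without control male 1, or in other neurons without control male 3.

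Fkbp5 stood at 23.3 ± 6.50 CPM (SD, n = 6) in control oligodendrocytes, 258 in those of both hungry samples and 113 and 149 in those of the sated male and female. In microglia it was at 138 ± 48.1 CPM (SD, n = 6) in controls, 1152 and 1120 in the hungry male and female and 462 and 664 in the sated ones. Dopaminergic nuclei held 33.9 ± 6.50 CPM (SD, n = 6) in controls, 28.9 and 36.6 in the hungry and 23.8 and 25.5 in the sated male and female (−0.19, adjusted p = 0.680). Between hungry and sated mice, Fkbp5 was higher in the hungry in oligodendrocytes (0.95, adjusted p = 0.0380) and microglia (1.01, 0.0389), whereas its value of 1.5 in astrocytes did not pass (0.0775). Plin4 was higher in hungry oligodendrocytes (1.22, 0.0258) and astrocytes (2.30, 0.0258), and Cdkn1a in hungry oligodendrocytes (1.80, 0.0409). All 15 members in oligodendrocytes passed with any 1 library left out.

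**Figure D2:**
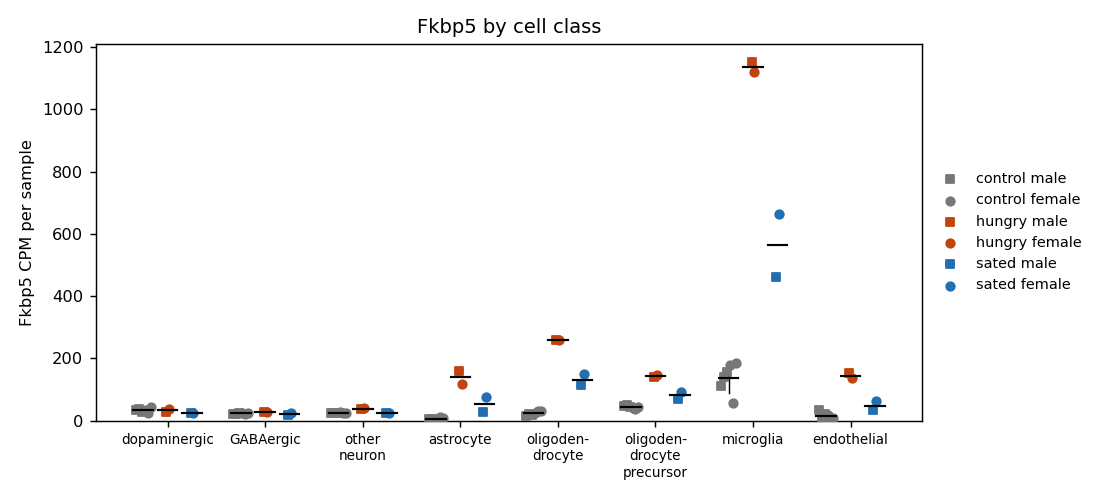
Fkbp5 in CPM (vertical axis) in summed nuclei of 8 classes (horizontal axis) of each sample, with controls in grey, hungry samples in red and sated samples in blue, squares for male and circles for female samples, short horizontal bars for group means and vertical lines for the SD of the 6 controls. In oligodendrocytes and microglia the 4 hungry and sated samples lie above the control means of 23.3 and 138 CPM, while in dopaminergic nuclei the hungry and sated samples lie between 23.8 and 36.6 CPM, near the control mean of 33.9 CPM.

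Females and males were compared in dopaminergic nuclei to look for differences between the sexes. The genes that differed were X- and Y-linked, and they went with the sex labels in every sample. Xist, the RNA that silences an X chromosome, stood at 994 ± 59.9 CPM in females and 0.220 ± 0.33 CPM in males (SD, n = 5 each), with adjusted p = 1.72e-18 from edgeR. Its antisense partner Tsix was at 315 ± 76.6 and 0.292 ± 0.399 CPM (6.70e-15), a value that cannot be told apart from Xist without strand. Kdm5c, an X-linked histone demethylase that escapes inactivation, was at 75.9 ± 5.37 CPM in females and 47.8 ± 9.08 CPM in males (0.69, SE 0.119, adjusted p = 0.0291). The Y-linked Uty (132 ± 12.9 CPM in males and 0.479 ± 0.323 in females, adjusted p = 6.70e-15), Kdm5d (67.3 ± 8.89 and 0.454 ± 0.547, 8.01e-12), Eif2s3y (125 ± 17.3 in males and no UMI in any female, which allows up to 3 UMIs per sample, 8.04e-11) and Ddx3y (48.3 ± 5.49 and 0.834 ± 0.550, 1.30e-10) were higher in males. No other gene passed, so the total was 3 rising and 4 falling of 12831, and DESeq2 called 7. Kdm6a (0.67, adjusted p = 0.0915), Eif2s3x (0.74, 0.599) and Vip (−2.09, 0.343) came next and did not pass. Th (0.28), Slc6a3 (0.04), Lepr (−0.06), Insr (−0.08), Esr1 (−0.03) and Fos (−1.04) did not pass either (Th at adjusted p = 0.997).

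Among gene lists, oxidative phosphorylation genes lay lower in females (22 of 23 members, median −0.27, camera adjusted p = 2.47e-08), as did mitochondrially encoded genes (13 of 13, median −0.51, 8.96e-06), cholesterol synthesis genes (15 of 20, median −0.12, 0.00810) and immediate early genes (10 of 12, median −0.33, 0.0167). No member passed over all genes or adjusted over the list alone, and each of these 4 lists had adjusted p = 0.513 with an estimated correlation. Feeding-hormone genes had 9 of 11 members lower (median −0.08), with adjusted p = 0.0408 by fry and 0.110 by camera. The other lists did not pass camera: stress 0.0645, glutamate and GABA receptor 0.0925, dopamine subtype 0.0925, GABAergic 0.127, oligodendrocyte 0.127 and potassium channel 0.154. Adjusted p-values were 0.213 for neuropeptide, 0.320 for glucocorticoid-responsive, 0.472 for fatty acid, 0.472 for oligodendrocyte precursor, 0.549 for social-hormone, 0.549 for dopamine handling and 0.978 for astrocyte genes, and 0.756 each for clock, insulin and FoxO, microglia and endothelial genes. Adjusted over the list alone, 1 neuropeptide and 1 dopamine subtype gene fell. In the other classes 7 genes differed by sex in GABAergic neurons, 8 in other neurons, 8 in astrocytes, 6 in oligodendrocytes, 7 in oligodendrocyte precursors and 5 each in microglia, endothelial cells and fibroblasts. Leaving out a library moved the astrocyte count to 5 without control male 1 and 15 without the hungry male, the microglia count to 16, 11, 22 and 37 without the hungry male, hungry female, sated male and sated female, and the endothelial count to 11 and 12 without the sated male and female.

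Dopaminergic nuclei made up 5.43% ± 2.19 of nuclei in females and 3.32% ± 0.759 in males (SD, n = 5 each), a difference with p = 0.0397 by a two-sided exact permutation test and 0.397 after adjustment over 10 classes. No class differed between the sexes after adjustment. Oligodendrocytes were 31.3% ± 8.84 of control nuclei (SD, n = 6), 24.2% and 32.2% in the hungry male and female and 31.7% and 29.6% in the sated ones. Shares depend on the punch and on which nuclei survive capture, and the 18 unnamed clusters are not in any class.

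Receptors for feeding-related and social hormones were examined together to ask whether the same dopaminergic nuclei express both. In nuclei thinned to 2000 UMIs, Ntsr1, a neurotensin receptor, had a UMI in 22.1% ± 3.15 of dopaminergic nuclei (SD over 10 samples) against 1.52% of oligodendrocyte nuclei thinned alike, the leptin receptor Lepr in 8.27% ± 1.28 against 0.380%, the orexin receptor Hcrtr2 in 4.34% against 0.380%. Likewise, a UMI was seen of the opioid receptor Oprm1 in 14.1% ± 3.01 against 1.14%, and of the receptors for progesterone (Pgr), prolactin (Prlr) and estrogen (Esr1) in 8.19%, 6.07% and 3.38% against 0.760%, 1.06% and 0.152%. Insr (19.8% ± 1.5 against 23.7%), Adipor1 (4.65% against 5.78%) and Adipor2 (7.92% ± 1.28 against 76.1%) were no more frequent in dopaminergic than in oligodendrocyte nuclei, and the ghrelin receptor Ghsr (0.490% against 0.228%) and the oxytocin receptor Oxtr (0.159% against 0.152%) were rare in both. The thinned oligodendrocyte values were pooled over the 1316 nuclei with at least 2000 UMIs, of 34920 in that class. Without thinning, Lepr had a UMI in 13.2% and Oxtr in 0.254% of dopaminergic nuclei (median 3388 UMIs), against 0.143% and 0.112% of oligodendrocyte nuclei (median 981 UMIs). No UMI of Glp1r, Gcgr or Avpr1b was seen in the 3870 thinned nuclei, which allows up to 3 such nuclei for each gene, by counting error only.

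At least 1 feeding-hormone gene was detected in 56.3% ± 2.5 and at least 1 social-hormone gene in 34.3% ± 2.5 of thinned dopaminergic nuclei (SD over 10 samples), against 85.0% and 4.86% of oligodendrocyte nuclei thinned alike. Nuclei with both did not differ in number from what independence would give. The log2 ratio of observed to expected nuclei averaged 0.024 ± 0.096 (SD over 10 samples), ranged from −0.11 in control female 2 to 0.20 in control male 3 and was above 0 in 5 of 10 samples (two-sided exact sign-flip permutation test, p = 0.457). Random pairs of lists matched on detection gave −0.063 to 0.058 in the central 95%, with the measured pair at percentile 76.1. Without thinning the ratio was 0.072, above 0 in 10 of 10 samples (exact p = 0.00195, the smallest that 10 samples allow), in nuclei that differ in depth. The mean was 0.0236 ± 0.101 in females and 0.0244 ± 0.103 in males (SD, n = 5 each, exact permutation p = 1), −0.0030 ± 0.106 in controls (SD, n = 6), 0.056 in the hungry and 0.073 in the sated samples. The hungry mean changed sign to −0.208 at 1000 UMIs, −1.06 with at least 2 UMIs of each list, −0.0389 with doublets kept, −0.00478 with the left-out cluster and −0.0125 with another seed, while the sated mean stayed above 0. None of 30 gene pairs passed after adjustment. Nuclei with both Lepr and Esr1 numbered 1.61 per 1000 against 2.87 expected (above expectation in 1 of 10 samples, exact p = 0.00586, adjusted p = 0.117).

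**Figure D3:**
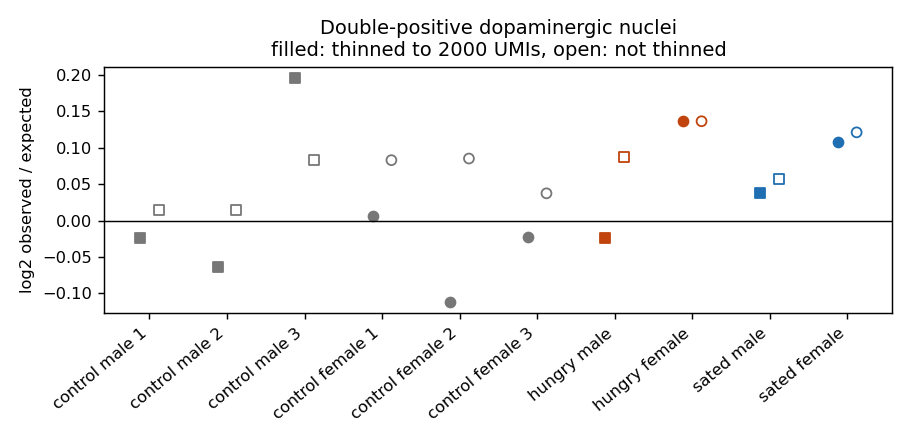
Log2 ratio of observed to expected dopaminergic nuclei with both a feeding-hormone and a social-hormone gene (vertical axis) in each of the 10 samples (horizontal axis, by condition and sex), with filled points for nuclei thinned to 2000 UMIs and open points for nuclei not thinned. The filled points scatter around 0, from −0.11 to 0.20, and all 10 open points lie above 0.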

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

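The checks in this part were fixed before the data were examined, except where stated, and no explanation was tested for any of the values. Each of 74 values was examined in the 6 control samples for a sample whose gap to its nearest neighbour exceeded Dixon's 95% critical value of 0.625 of the whole range. Of these, 9 did, where chance gives about 1 in 20. Control female 3 had the highest share of called doublets, 7.84%, with the nearest control at 5.28%. Control female 2 had the lowest share of oligodendrocytes, 13.8% against 31.6% in the nearest control, and of microglia, 0.321% against 2.18%. In dopaminergic nuclei, control male 2 was highest for Esr1 (27.0 CPM, nearest control 14.9) and for Ndrg2 (52.1 CPM, nearest 33.9). Control male 1 was highest for Fos (16.4 CPM, nearest 3.57). Control male 3 was highest for Insr (133 CPM, nearest 116) and lowest for Tmem145 (44.2 CPM, nearest 67.0). Control female 1 was lowest for Slc1a3 (3.39 CPM, nearest 5.16).

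The change between hungry and sated mice differed between the sexes for 187 genes in dopaminergic nuclei (edgeR interaction term, 127 with a higher log2 fold change in females and 60 with a lower one), with 1 sample per sex and condition. Genes of lowest p were 4930558K02Rik (female minus male log2 fold change −4.50), Acoxl (−6.71), Hbb-bs (3.99) and Cdh23 (−4.44), all at adjusted p = 4.22e-04, and the neuronal non-coding RNA Bc1 (−1.94, adjusted p = 0.00107). Of the 20 genes of lowest p, 7 encode subunits of oxidative phosphorylation, with differences from 2.54 (Ndufa13) to 3.92 (Ndufb7), a feature chosen after the values had been seen. The term sets the hungry female and the sated male against the hungry male and the sated female, as does the split of the 10 samples with the most genes in 7 of 9 classes. A difference between these libraries is therefore not set apart from one between the sexes. The spread in this test comes from the controls alone, so its p-values do not measure variation between hungry or sated pools. Bc1 stood at 331 ± 31.4 CPM (SD, n = 6) in controls, 801 and 572 in the hungry male and female, 638 in the sated male and 1768 in the sated female. None of the genes named by the fixed rule for hungry against sated mice in dopaminergic nuclei was among the genes whose change differed between the sexes. That outcome was favoured in advance. The rule asked for the same direction in both sexes, and a difference between the sexes widens the spread in the fit that called the genes. It therefore does not show that their change was alike in both sexes. Whether the change differed between the sexes was not examined for the list members given as examples.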

How the results depend on the processing

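Alternatives chosen after the data had been seen were the other clustering seed, the left-out cluster, the same cluster mix, each dopaminergic cluster alone and the removal of ribosomal, mitochondrial and haemoglobin genes. Of 435 counts and single-value tests, 270 stayed on their side of the threshold with the same direction or within 1.5 times, 152 moved, 1 passed newly and 12 changed sign. Of 2925 fits of named genes, 2461 kept direction and call, 379 lost the call, 25 gained it, 24 moved and 36 changed sign. Shares of lost calls were largest from the hungry and sated samples alone (12 of 19), in cluster N9 (33 of 71) and without the hungry male (67 of 151). The cause was not tested. Depth limits genes such as Ghsr and Oxtr, and software version coincides with control status.

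For hungry against sated dopaminergic nuclei (17 genes) the counts were 353 with no low-count filter, 53 with DESeq2 (10 shared), 37 with at least 1000 genes per nucleus, 47 with another seed (15 shared), 0 from the hungry and sated samples alone (493 at unadjusted p under 0.05 in edgeR), 35 with no sex term, 44 with the same cluster mix, 91 with the left-out cluster (16 shared) and 29 in cluster N9. Against control, hungry nuclei (85) gave 472 with no filter, 128 with another seed, 240 with the left-out cluster and 22, 42 and 44 in clusters N2, N24 and N9. Sated nuclei (122) gave 431 with no filter, 50 and 33 in clusters N24 and N9 and 78 without ribosomal, mitochondrial and haemoglobin genes. Both together (131) gave 481 with no filter, 208 with the left-out cluster and 81, 53 and 16 in clusters N2, N24 and N9. Female against male gave 11 with no filter.

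In other classes, hungry against sated gave with no filter 201 (GABAergic), 75 (other neuron), 441 (astrocyte), 507 (precursor), 169 (microglia), 20 (endothelial) and 164 (fibroblast), with DESeq2 343 (GABAergic), 275 (other neuron), 276 (astrocyte), 794 (oligodendrocyte), 2 (endothelial) and 15 (fibroblast), with at least 1000 genes 36 (GABAergic), 66 (astrocyte), 159 (oligodendrocyte) and 0 (endothelial, edgeR, 177 at unadjusted p under 0.05), with another seed 40 (GABAergic) and 9 (other neuron), and with doublets kept 2 (endothelial). Female against male gave with no filter 12 (microglia) and 8 (endothelial), with DESeq2 10 (oligodendrocyte), and from controls alone 3 (endothelial) and 2 (fibroblast).

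Replicate numbers do not pair the sexes: same-numbered control samples correlated at −0.002, −0.048 and −0.118, and not every sample correlated best with its own number. With the replicate number as a block, female against male in dopaminergic nuclei again gave 7 genes, 6 of them shared. Controls alone with the block gave 23 (astrocyte), 38 (oligodendrocyte) and 18 (microglia), against 8, 9 and 6 without it, and again 3 (endothelial) and 2 (fibroblast). The block changed no other count by over 1.5 times.

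Gene lists past the threshold numbered 0 in each of the 3 contrasts with an estimated correlation, and 0, 0 and 1 with fry for a shared direction (hungry against sated, both against control, female against male). Co-expression (0.024) was 0.0721 without thinning (p = 0.00195), −0.012 at 1000 UMIs (p = 0.816), −0.0048 with the left-out cluster (p = 0.873) and −0.0078 with another seed (p = 0.711), all by exact sign-flip tests. Its female minus male difference was 0.0413 without thinning, 0.0119 with doublets kept, 0.134 without the most detected gene (exact permutation p = 0.0556) and 0.0167 with the left-out cluster.

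Receptor and marker genes that never passed changed sign as follows on the log2 scale. Hungry against sated: Lepr −0.047 with the same mix, −0.040 in N2 and −0.161 in N24. Both against control: Lepr −0.066 in N24, Slc6a3 −0.089 in N9, Fos 0.013 with the left-out cluster, and Esr1 8.0e-04 with RLE, 0.0015 with no filter, 0.059 with 1000 genes, 0.055 with the same mix, 0.024 with the left-out cluster and 0.0025 in N24. Female against male: Insr 0.016 with the left-out cluster and 0.014 in N24, Lepr 0.013 with the left-out cluster, 0.047 in N24 and 0.084 in N9, Slc6a3 −0.059 in N24, and Esr1 0.035 with the same mix and 0.104 in N24.

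Leaving out each sample in turn gave, for hungry against sated in dopaminergic nuclei, 0 (without the hungry male, edgeR, 753 at unadjusted p under 0.05) to 607 genes (without the sated female), for hungry against control 0 (810) to 252, for sated against control 17 to 511, for both against control 23 to 228 and for female against male 6 to 7. Hungry against sated gave 0 to 1034 (GABAergic), 0 to 711 (other neuron), 1 to 1222 (astrocyte), 0 to 2160 (oligodendrocyte), 9 to 949 (precursor), 4 to 721 (microglia), 0 to 203 (endothelial) and 8 to 120 (fibroblast), and female against male 6 to 7, 6 to 7, 5 to 15, 6 to 8, 6 to 7, 5 to 37, 5 to 12 and 5 to 6. Co-expression ranged from 0.00487 to 0.0391, and its sex difference from −0.0291 to 0.0421. Named genes that changed sign ranged, for hungry against sated, from −0.045 to 0.43 (Insr) and −0.68 to 0.30 (Esr1), for both against control from −0.17 to 0.072 (Insr), −0.013 to 0.12 (Slc6a3) and −0.24 to 0.26 (Esr1), and for female against male from −0.16 to 0.024 (Insr), −0.042 to 0.11 (Slc6a3) and −0.25 to 0.20 (Esr1).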

Other observations

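All list members outside dopaminergic nuclei and all tests in this part were chosen after the results had been seen. In oligodendrocytes of hungry and sated mice together, against controls, 8 of 18 clock genes rose, among them the period genes Per2 (2.0), Per1 (1.72) and Per3 (0.67), Cry1 (0.95) and Dbp (0.77), with no member falling (camera adjusted p = 8.53e-04, and adjusted p = 0.236 with an estimated correlation). In astrocytes Per1 (1.2), Per2 (0.83), Bhlhe41 (0.56) and Tef (0.46) rose while Nr1d1 (−0.76) and Arntl (−0.66) fell. Genes of cholesterol synthesis and uptake fell in oligodendrocytes, the cells that make myelin: 7 of 20 passed, among them Dhcr7 (−0.91, adjusted p = 5.36e-04) and their regulator Srebf2 (−0.49, 0.00389), with a median of −0.41 (camera adjusted p = 1.04e-05, and adjusted p = 0.355 with an estimated correlation). In endothelial cells 11 of 13 glucocorticoid-responsive genes rose, with Zbtb16 at 3.33 and Fkbp5 at 2.84.

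The first pattern is that the 14 genes lower in hungry than in sated dopaminergic nuclei were lower in nearly every class. At least 92.86% of them had negative fold changes in oligodendrocytes, astrocytes and microglia, cells that should not make neurofilaments. Free RNA in the droplets that differs between these libraries may therefore account for them. The higher mitochondrial share of the sated samples goes the same way, but among controls that share did not go with these genes throughout. In dopaminergic nuclei, control male 3 (share 1.80%) held 18.4 CPM of Nefm and 13.3 CPM of Pvalb. Control female 1 (0.142%) held 20.8 and 12.6 CPM. Nefl (46.4 against 37.3 CPM) and Aldoc (44.9 against 23.7 CPM) were higher in control male 3, though below both sated samples. Another mix of clusters N2, N24 and N9 was excluded as the whole cause, since the median log2 fold change was −1.419 at the same mix against −1.342. The left-out cluster was not part of that mix. Without the sated male library the median was −1.199, so the sated female also lay above the hungry samples for these genes. The genes had been chosen in a fit that held all these libraries, so dependence on single libraries is not excluded. A response of neurons to feeding state stays open and was not tested apart from free RNA.

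The second pattern is that 131 genes differed between controls and the other samples. Of 100 splits of the 10 samples, only the real one (1) gave as many genes, with 85 in the highest of the others. A chance division of the libraries is argued against by this count but not excluded. Only a draw of the possible splits was run. In the other splits a difference from controls also widens the spread, which lowers their counts. Between 90.16% and 98.47% of these genes had the same sign in GABAergic neurons, astrocytes and oligodendrocytes, as another software version in read counting could also give. Free RNA that differs between libraries could give shared signs too and was not tested for these genes. Software, any shared day of work and the manipulation of feeding cannot be told apart here, because every control file came from 1 version and every other file from the other.

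The third pattern is the rise of glucocorticoid-responsive genes in glia of hungry and sated mice. A software effect of the same size in all classes was argued against. The log2 fold change in oligodendrocytes exceeded that in dopaminergic nuclei by a median of 1.382 (10 members, all larger in oligodendrocytes). A change in read counting whose effect differs between classes was not tested and stays open. Free RNA was argued against for most members, because the gain in UMIs per nucleus in dopaminergic nuclei was a median of 0.0963 times that in oligodendrocytes. The ratio was higher for Mt1 (0.879), Sult1a1 (0.836), Mt2 (0.830) and Per1 (0.588), for which free RNA stays open. Another time of day at collection stays open, since 8 clock genes rose in oligodendrocytes and Per1 belongs to both lists. A response to the manipulation of feeding and any shared day of work stay open as well and were not tested.

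Other splits of the samples bear on the sex comparisons. With 7 genes in dopaminergic nuclei, 6 of 100 splits gave as many, the real one included, and the highest other gave 206. In the other classes, the splits with as many genes, of 40, were 4 in GABAergic neurons (7 genes, highest other 153), 4 in other neurons (8, 470), 6 in astrocytes (8, 903), 3 in oligodendrocytes (6, 798), 6 in oligodendrocyte precursors (7, 404), 8 in microglia (5, 243), 8 in endothelial cells (5, 148) and 5 in fibroblasts and meningeal cells (5, 72). By this count chance is not excluded for the number of genes in any class. The count does not bear on which genes were called. In dopaminergic nuclei the 7 genes were X- or Y-linked and went with the sex labels. Their levels, given above, argue against chance for Xist, Tsix and the Y-linked genes. The split with the most genes in most classes set control female 1, control males 1 and 3, the hungry female and the sated male against the rest. What it reflects was not tested, and a feeding change that differs between the sexes is not set apart from it. For gene lists, 58 of 100 splits gave at least the 4 lists of the sex contrast (highest other 9) and 67 of 100 at least the 4 of hungry and sated mice against controls (highest other 11), so chance is not excluded for either.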
